A study of Drosophila melanogaster with 18 samples.

How the data were processed

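RNA was sequenced from adult male w1118 Drosophila melanogaster after injection of PBS or M. luteus, at 3, 12 and 24 h, with 3 libraries per treatment and time. Per the labels, total RNA was taken with Trizol, its integrity was checked on a Bioanalyzer, and standard Illumina libraries were made. The authors mapped reads to dm6 with TopHat2 2.0.9 and Bowtie2 2.0.0 after a FastQC check and estimated expression with Cufflinks 2.1.1. The deposited values are FPKM per assembled locus, 16756 loci in 18 libraries. The annotation release, the strandedness and any filter behind the table are not given in the sources used here. The table came on sheets with identical values (0 differing). No pair of the 153 library pairs was identical, and at least 86.6% of loci differed in each pair.

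Read counts were not used here, so the depth of each library, and with it the counting error of each value, is unknown. Depth could not be recovered from the lowest values either: the ratio read from only 36 of the 153 pairs of libraries lay within 0.05 on the log2 scale of the joint estimate over all pairs. FPKM sums over loci ranged from 996325 to 1494569 per library.

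Of the loci, 15294 carried 1 gene identifier, 1035 several and 427 none, and all identifiers were matched to current symbols for 16111. Loci merged from several genes were kept as 1 value under their joined symbols. Coordinates are those of the assembled locus and may exceed the gene. Of the loci, 29 with a failed estimate in any library were left out, and loci with at least 1 FPKM in at least 3 of the 18 libraries were tested, 12493 in all.

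Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. One model with 6 group means was fitted (residual degrees of freedom 12), with moderated variances and a trend on mean expression (prior degrees of freedom 2.73). Contrasts were M. luteus minus PBS at each time, the mean of these, their differences between times, and the PBS groups between times. Tests were two-sided, and p-values were adjusted per contrast by the Benjamini-Hochberg method with a threshold of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Fold values are 2 raised to the fitted log2 change, not ratios of the mean FPKM.

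The comparisons, the alternatives, 39 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 952 names, of which 7 could not be resolved, 30 had no locus and 97 lay on loci merged with a gene outside the list and were left out; names of the same gene within a list counted once, and 814 memberships were used. Lists with at least 5 tested members (37) were tested with camera at its preset correlation of 0.01, and again with a correlation estimated per list. The named genes of each infection contrast, of the mean effect and of each difference between times are the 10 largest rises and 10 largest falls among genes past the threshold. For infection contrasts and the mean, all 3 M. luteus libraries also had to lie on one side of the 3 PBS libraries at each time concerned. For the PBS contrasts the 5 largest each way were taken, and any member of a fixed list could be named.

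The procedure was tested on simulated data, with changes added to 50 genes per size. Noise was drawn independently for each gene, with the same spread in every library, and changed genes had a mean log2(FPKM + 1) over 2. The simulation held no outlying libraries and no correlation between genes. Its rates therefore do not carry over to weakly expressed genes or to groups with libraries that stood apart. At 3 h the test called 24, 40, 48 and 49 of 50 genes changed 1.5, 2, 4 and 8-fold, at 12 h 30, 38, 49 and 50, and at 24 h 37, 45, 47 and 49. Among the unchanged genes it called 4, 15 and 6. Alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization, the replicate number as a block, array weights, robust moderation, the compared libraries alone, an added 2-fold minimum, and each library left out. For the lists, fry (directional and mixed) was run as well. Leaving out the 24 h libraries, alone or with PBS 3 h replicate 3, was added after the data were seen.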

Results

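Gene expression was measured by RNA sequencing in adult male Drosophila melanogaster of the w1118 strain, a laboratory background that lacks normal eye pigment. Flies were injected with Micrococcus luteus, a Gram-positive bacterium whose cell wall is sensed by the Toll pathway, or with phosphate-buffered saline (PBS), which gives the injury without the bacteria. Each treatment was sampled at 3, 12 and 24 h with 3 libraries per group, 18 libraries in all. The labels do not say whether the 3 libraries of a group came from separate batches of flies, so the p-values measure the spread between these libraries. Values are FPKM (mapped fragments scaled by transcript length and library total), and the read depth behind them is unknown. Summed over all loci, FPKM ranged from 996325 to 1494569 per library, and 11607 to 11938 loci reached 1 FPKM.

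Within each time, M. luteus was compared with PBS to measure the response to the bacteria beyond that to the injury, and the response was then compared between times. Log2 changes are differences of log2(FPKM + 1), a scale that understates changes of weakly expressed genes. They are given with their standard error (SE), FPKM with the standard deviation (SD) of 3 libraries, and p-values are adjusted by the Benjamini-Hochberg method. Of 12493 genes tested, 717 changed at 3 h, 986 at 12 h and 417 between the groups as labelled at 24 h.

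**Figure D1:**
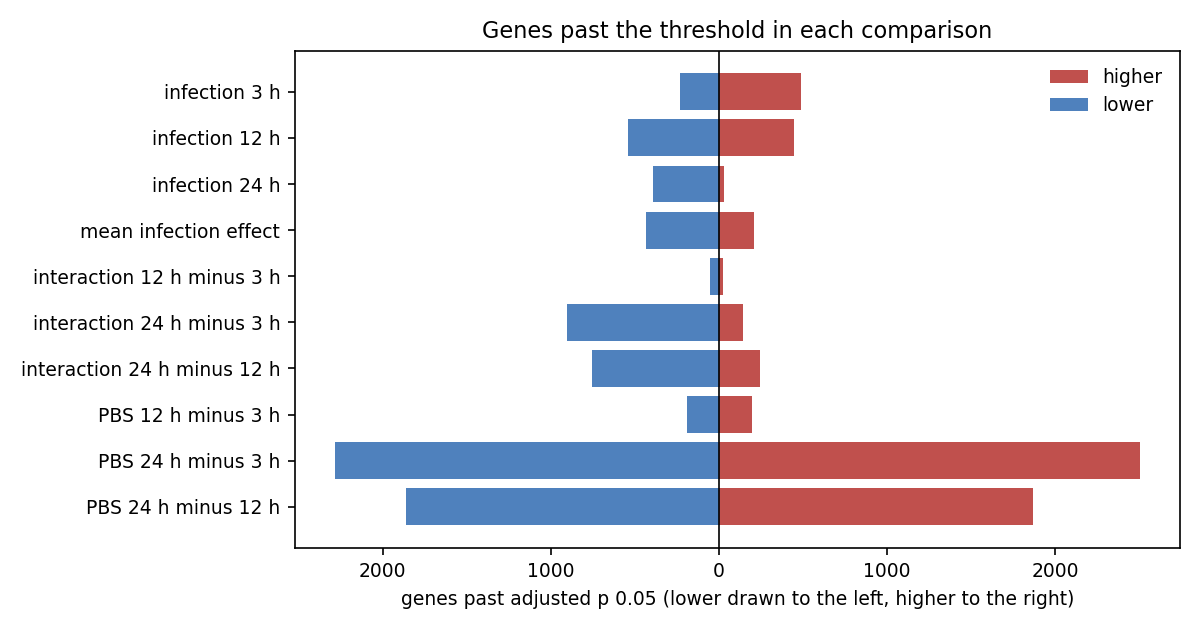
Number of genes past an adjusted p of 0.05 in each comparison, with genes that were lower drawn to the left of 0 and genes that were higher to the right. At 3 h, 487 genes were higher and 230 lower in M. luteus; at 12 h, 444 were higher and 542 lower; at 24 h, as labelled, 27 were higher and 390 lower.

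Several libraries stood apart in transcripts that the groups do not name. PBS 3 h replicate 3 held the transcripts of the list of ovary and female fat body genes at a mean log2(FPKM + 1) of 7.27, against at most 0.65 in the other 17 libraries. M. luteus 3 h replicate 2 was low in eye transcripts, with a mean of 1.34 over 18 loci. In it ninaE, the main rhodopsin of the outer photoreceptors, was at 9.47 FPKM, against 2532 and 1394 in the other M. luteus 3 h libraries. At 24 h, bomanins such as BomS1 differed strongly between libraries of the same label, as given with that comparison. Because all groups share one estimate of spread, the counts at 3 and 12 h are also given without the 24 h libraries.

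**Figure D2:**
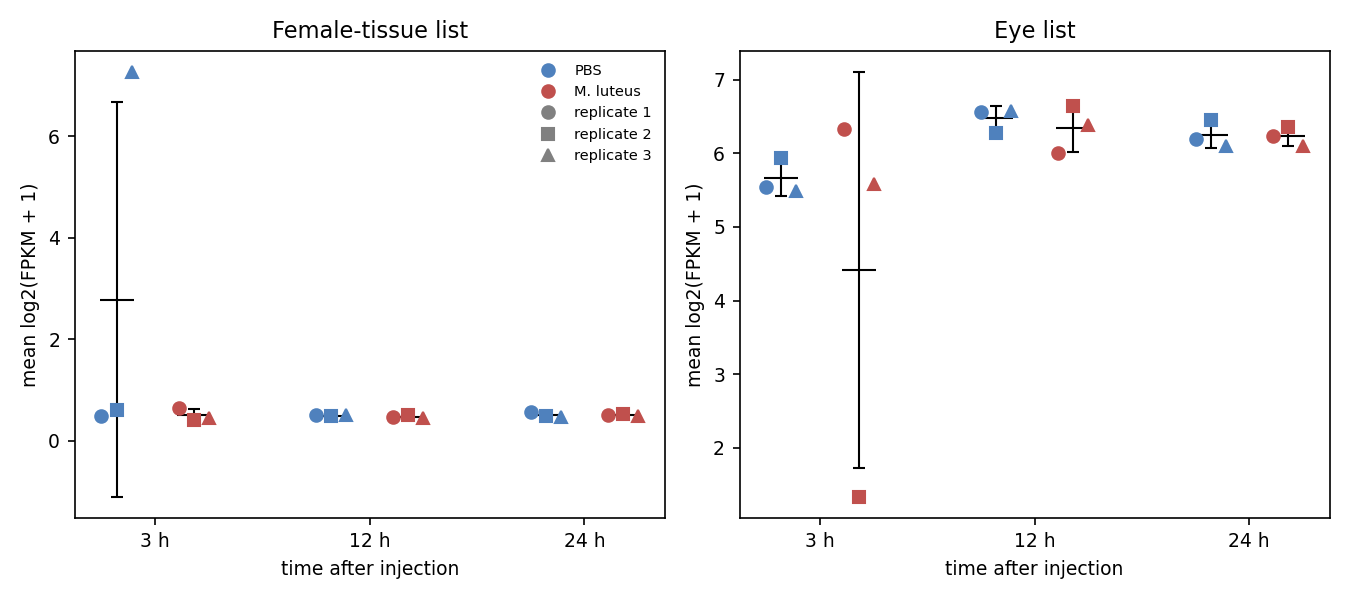
Mean log2(FPKM + 1) of the female-tissue list and of the eye list in each library, by group; points are libraries, and lines and bars are the mean and SD of 3 libraries. PBS 3 h replicate 3 lies at 7.27 for the female list and M. luteus 3 h replicate 2 at 1.34 for the eye list.

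At 3 h, antimicrobial peptide genes were among the largest rises after M. luteus, behind CG14499 (log2 change 5.33), CG42662 (5.29) and BomT1 (4.47). Attacin-D (AttD, FBgn0038530, dm6 chromosome 3R, 17625268 to 17626086) averaged 208 ± 52.0 FPKM after M. luteus and 9.79 ± 3.09 after PBS (SD, n = 3 each), 19.6-fold higher (log2 change 4.29 ± 0.53 SE, adjusted p = 0.00067). The cecropin CecA1 reached 4654 ± 1745 FPKM against 423 ± 111, 10.8-fold higher, and CecB 246 ± 81.5 against 11.8 ± 2.08. Of 19 antimicrobial peptide loci, 8 rose and none fell, or 10 when adjusted over the list alone. The merged locus of AttA and AttB, near-identical genes that the table does not separate, was among them at 1.75 ± 0.47 (adjusted p = 0.0435). The list's camera test gave an adjusted p of 1.2e-06, and adjusted p = 0.18 with an estimated correlation.

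Some signalling genes of both immune pathways rose as well. Of 13 core Toll pathway genes 5 rose and 1 fell at 3 h, the same numbers when adjusted over the list alone. The risers included spz, the ligand of the Toll receptor (log2 change 0.97), Dif, a transcription factor of the pathway (0.89), and the kinase pll (adjusted p = 0.0221). Of 18 extracellular recognition proteins, proteases and serpins upstream of Toll, 8 rose and none fell (12 when adjusted over the list alone), among them PGRP-SA, a recognition protein for Gram-positive peptidoglycan, at 456 ± 15.4 FPKM against 134 ± 13.0, and the protease spirit (2.11). Of 20 genes of the IMD pathway, the other main antibacterial pathway, 5 rose and none fell, also 5 when adjusted over the list alone, including imd itself (1.17 ± 0.15 SE, adjusted p = 0.00088) and its transcription factor Rel (237 ± 28.5 FPKM against 64.6 ± 12.5). Among 16 negative regulators 6 rose and none fell (8 when adjusted over the list alone). The largest of these rises was that of pirk, an inhibitor of IMD signalling, at 74.0 ± 17.7 FPKM against 6.84 ± 2.72, or 9.77-fold, and cact, the inhibitor of Dif, rose by 1.57. Of 11 peptidoglycan recognition proteins 5 rose (7 when adjusted over the list alone), with PGRP-SC2 at 2.22. Camera adjusted p-values were 0.0032 for the Toll core, 6.4e-08 for the upstream proteases, 0.0013 for IMD, 1.0e-06 for the negative regulators and 3.3e-06 for the recognition proteins. In the same order they were adjusted p = 0.41, 0.18, 0.37, 0.18 and 0.18 with an estimated correlation. Without the 24 h libraries those of the upstream proteases, the negative regulators and the recognition proteins passed, with adjusted p = 0.0285, 0.0285 and 0.0441 with an estimated correlation.

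The bomanins, short secreted peptides made downstream of Toll, and the related Daisho peptides were variable in the joint fit at 3 h. BomS1 (FBgn0034329, chromosome 2R, 18383949 to 18384378) averaged 9738 ± 2466 FPKM against 1523 ± 465, yet its adjusted p was 0.243 (log2 change 2.69 ± 1.30 SE), with the 24 h spread in the shared variance. Drosomycin (Drs), the antifungal peptide that serves as the standard Toll readout, was at 5518 ± 824 against 1393 ± 123 FPKM (adjusted p = 0.156). Of 15 bomanin and Daisho loci, only BomT1 passed (4.47 ± 1.21, adjusted p = 0.0447), also 1 when adjusted over the list alone. The camera adjusted p of the list was 0.0033, and adjusted p = 0.54 with an estimated correlation. Without the 24 h libraries 11 of the 15 rose, with adjusted p = 0.029 with an estimated correlation.

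Part of the secretion and detoxification lists rose. Of 22 genes of the endoplasmic reticulum stress and secretion list 9 rose and none fell (15 when adjusted over the list alone), with camera adjusted p = 1.1e-10 and adjusted p = 0.18 with an estimated correlation. The nucleotide exchange factor Sil1 (FBgn0039296, chromosome 3R, 25233636 to 25235529) rose 2.81-fold (log2 change 1.49 ± 0.12, adjusted p = 2.9e-05). Its partner chaperone Hsc70-3, known as BiP, rose to 752 ± 59.8 from 453 ± 54.9, and the chaperone Gp93 rose by 0.89 ± 0.15. In the list for oxidative stress and detoxification, 5 of 25 genes rose and none fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0010, and adjusted p = 0.26 with an estimated correlation). GstD2, a glutathione transferase, rose by 1.48 ± 0.31, and Keap1, the sensor that restrains the antioxidant factor CncC, by 0.85. Of 21 flight muscle genes, 7 rose and none fell (14 when adjusted over the list alone; camera adjusted p = 2.7e-09, and adjusted p = 0.18 with an estimated correlation). They included myosin heavy chain (Mhc), at 2378 ± 282 against 1574 ± 274 FPKM, and wupA, which encodes troponin I, at 0.57 ± 0.11.

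Of 12 melanization genes 5 rose and 2 fell at 3 h (8 and 2 when adjusted over the list alone; camera adjusted p = 0.00019, and adjusted p = 0.37 with an estimated correlation, or 0.0285 without the 24 h libraries). The protease Hayan, which activates prophenoloxidase, rose by 1.87. The 2 that fell were the prophenoloxidases PPO1 and PPO2, enzymes of crystal cells, at 2.69 ± 3.27 against 14.4 ± 6.91 FPKM and 5.15 ± 6.38 against 28.8 ± 14.6. Both these calls ended without PBS 3 h replicate 3, the library with female transcripts. Other falls were those of CG4716 (196 ± 74.6 against 887 ± 49.2 FPKM, adjusted p = 0.00026) and of the neprilysin-family peptidase Nep6 (7.18 ± 2.21 against 28.3 ± 5.01, adjusted p = 0.00012). In purine metabolism 3 of 10 genes fell and none rose (4 when adjusted over the list alone; camera adjusted p = 0.00092, and adjusted p = 0.18 with an estimated correlation). No gene of the eye list or of the cell cycle list changed at 3 h in limma (18 and 22 genes), although camera placed both lower, with adjusted p = 0.0032 and 5.0e-06, and adjusted p = 0.57 and 0.50 with an estimated correlation. The cell cycle list averaged 4.59 in PBS 3 h replicate 3 and 2.58 to 2.87 in the other libraries. Among other rises, CG14499 went to 132 ± 49.5 FPKM from 2.22 ± 0.70, and the lysozyme gene LysB to 44.3 ± 9.56 from 11.4 ± 2.85 (adjusted p = 0.00012). Its neighbour LysC, assembled over the same span, was listed at 0 in all 3 M. luteus libraries and at 155, 65.3 and 9.0 FPKM in PBS, which leaves the division of reads between these similar genes uncertain. The count of 717 was 1007 without the 24 h libraries and 837 without those and PBS 3 h replicate 3. It was 195 without M. luteus 3 h replicate 3 and 366 without PBS 3 h replicate 3.

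At 12 h, BomS1, Drs and other Toll effectors stood far above PBS. BomS1 averaged 21276 ± 588 FPKM after M. luteus and 345 ± 32.3 after PBS (SD, n = 3 each), 61.6-fold higher (log2 change 5.95 ± 1.30 SE, adjusted p = 0.0149). Drs (FBgn0283461, chromosome 3L, 3369556 to 3369942) reached 20582 ± 1207 against 915 ± 194 FPKM, 22.8-fold, and BomT1 396 ± 51.1 against 3.26 ± 0.25, 92.9-fold. The Daisho peptide gene Dso2 was at 32232 ± 858 against 1772 ± 293 FPKM. Of the 15 bomanin and Daisho loci 12 rose and none fell (13 when adjusted over the list alone; camera adjusted p = 1.2e-11, and adjusted p = 0.27 with an estimated correlation, or 0.0048 without the 24 h libraries). Of 19 antimicrobial peptide loci 8 rose (11 when adjusted over the list alone), with AttD at 274 ± 121 against 9.53 ± 4.90 FPKM, 26.2-fold. Of 18 extracellular recognition proteins, proteases and serpins upstream of Toll, 14 rose and none fell (14 and 1 when adjusted over the list alone). The camera adjusted p was 9.3e-09 for the peptides and 3.6e-10 for the proteases, and adjusted p = 0.24 with an estimated correlation for each, or 0.0238 for the proteases without the 24 h libraries. Of 13 core Toll genes 5 rose and none fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.00092, and adjusted p = 0.28 with an estimated correlation). The receptor Tl rose by 1.43, cact by 1.82, Rel by 2.07 and the serpin nec, which restrains the Toll cascade, by 2.80. SPH93, a serine protease homologue, went to 329 ± 3.57 from 2.94 ± 0.96 FPKM.

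Several metal-binding genes rose at 12 h. Metallothionein D (MtnD, FBgn0053192, chromosome 3R, assembled locus 20534962 to 20552311) averaged 61.6 ± 6.53 FPKM after PBS and was 17.5-fold higher after M. luteus (log2 change 4.13 ± 0.35, adjusted p = 9.8e-05). MtnA reached 11148 ± 1534 against 3320 ± 141, and MtnE rose by 2.01 ± 0.48. Transferrin 1 (Tsf1), the iron carrier of the hemolymph, was at 3996 ± 223 against 1228 ± 254. Of 10 genes of the iron and metal list, 6 rose and none fell (7 when adjusted over the list alone; camera adjusted p = 4.2e-08, and adjusted p = 0.24 with an estimated correlation, or 0.024 without the 24 h libraries). Tep2, a thioester protein of the opsonin family, rose by 2.44 ± 0.32. In the secretion list 7 of 22 rose (8 when adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.32 with an estimated correlation), including TRAM (0.91) and the translocon subunit Sec61alpha (0.57 ± 0.11).

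Part of the digestive, lipid and hemocyte lists fell at 12 h. Of 28 digestive proteases 11 fell and none rose (21 when adjusted over the list alone, camera adjusted p = 9.9e-13, and adjusted p = 0.27 with an estimated correlation). Their mean log2(FPKM + 1) was already lower at 3 h, at 6.07 to 6.54 after M. luteus against 6.92 to 6.94 after PBS. At 12 h it was 5.85 to 6.82 against 7.63 to 7.87, so the PBS libraries stood higher than at 3 h. Without the 24 h libraries, 7 of these genes were lower at 3 h and none higher. The gut serine protease Jon99Ci (FBgn0003358, chromosome 3R, 29925226 to 29926189) was at 57.4 ± 60.8 FPKM after M. luteus and 484 ± 57.2 after PBS (log2 change -3.55 ± 0.96, adjusted p = 0.0360), and Jon25Bi changed by -3.20 ± 0.88. Of 32 carbohydrate metabolism genes 5 fell and 2 rose (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0014, lower, and adjusted p = 0.41 with an estimated correlation). The 2 that rose were the amylase gene Amy-p, at 1.54 ± 0.17, and the maltase gene Mal-B1, at 1.32. Of 20 lipid metabolism genes, 6 fell and 1 rose (11 and 2 when adjusted over the list alone; camera adjusted p = 0.00049, and adjusted p = 0.27 with an estimated correlation). The lipoprotein precursor apolpp was at 94.5 ± 42.2 against 512 ± 96.0 FPKM, the lipase gene mag changed by -2.30 and the lipid droplet protein gene Lsd-1 by -1.70. Among 42 cytochrome P450 genes 15 fell and 3 rose (18 and 4 when adjusted over the list alone; camera adjusted p = 6.6e-07, and adjusted p = 0.27 with an estimated correlation), with Cyp6g1 at -1.70. The hexamerins Lsp1beta and Lsp2, storage proteins, were at 13.1 ± 8.45 against 163 ± 88.4 FPKM and at 0.50 ± 0.20 against 15.7 ± 4.38. Of 11 hemocyte genes 6 fell and none rose (7 when adjusted over the list alone, camera adjusted p = 5.1e-05, and adjusted p = 0.27 with an estimated correlation), including the phagocytosis receptor NimC1 (12.3 ± 4.69 against 37.7 ± 1.84 FPKM). These lowered lists did not pass camera with an estimated correlation without the 24 h libraries either. Adjusted p was 0.101 for the digestive and P450 lists, 0.181 for lipid and hemocyte genes, and 0.431 for carbohydrate metabolism. In that fit 5 carbohydrate, 5 lipid, 9 P450 and 4 hemocyte genes were already lower at 3 h, and 1 P450 gene was higher. Of 12 melanization genes 7 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.00054, and adjusted p = 0.28 with an estimated correlation, or 0.0341 without the 24 h libraries). The 2 that fell were PPO1 at -2.51 ± 0.56 and PPO2 at -2.29 ± 0.64. The collagen IV genes Col4a1 and vkg, made by hemocytes and fat body, changed by -1.36 ± 0.24 and -1.37 ± 0.23.

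The rises at 12 h also held CG4757, at 872 ± 412 against 8.48 ± 3.47 FPKM, and the falls Obp99b, an odorant-binding protein gene at 99.1 ± 70.9 against 1885 ± 438. The antisense locus asRNA:CR11538, at -4.96, spans the same coordinates as Lsp2, so its value is uncertain. The 986 genes became 1435 without the 24 h libraries, 1932 without these and PBS 3 h replicate 3, 1976 with only the 12 h libraries, and 220 without M. luteus 12 h replicate 1. They were 296 without M. luteus 12 h replicate 2 and 368, 333 and 360 without PBS 12 h replicates 1, 2 and 3. The balance of 444 higher and 542 lower turned in some of these fits. It was 126 higher and 94 lower without M. luteus 12 h replicate 1, and 177 and 119 without replicate 2. Without PBS 12 h replicates 1 and 2 it was 211 and 157, and 185 and 148. Without PBS 3 h replicate 3 it was 655 and 606. Without any other single library more genes were lower.

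**Figure D3:**
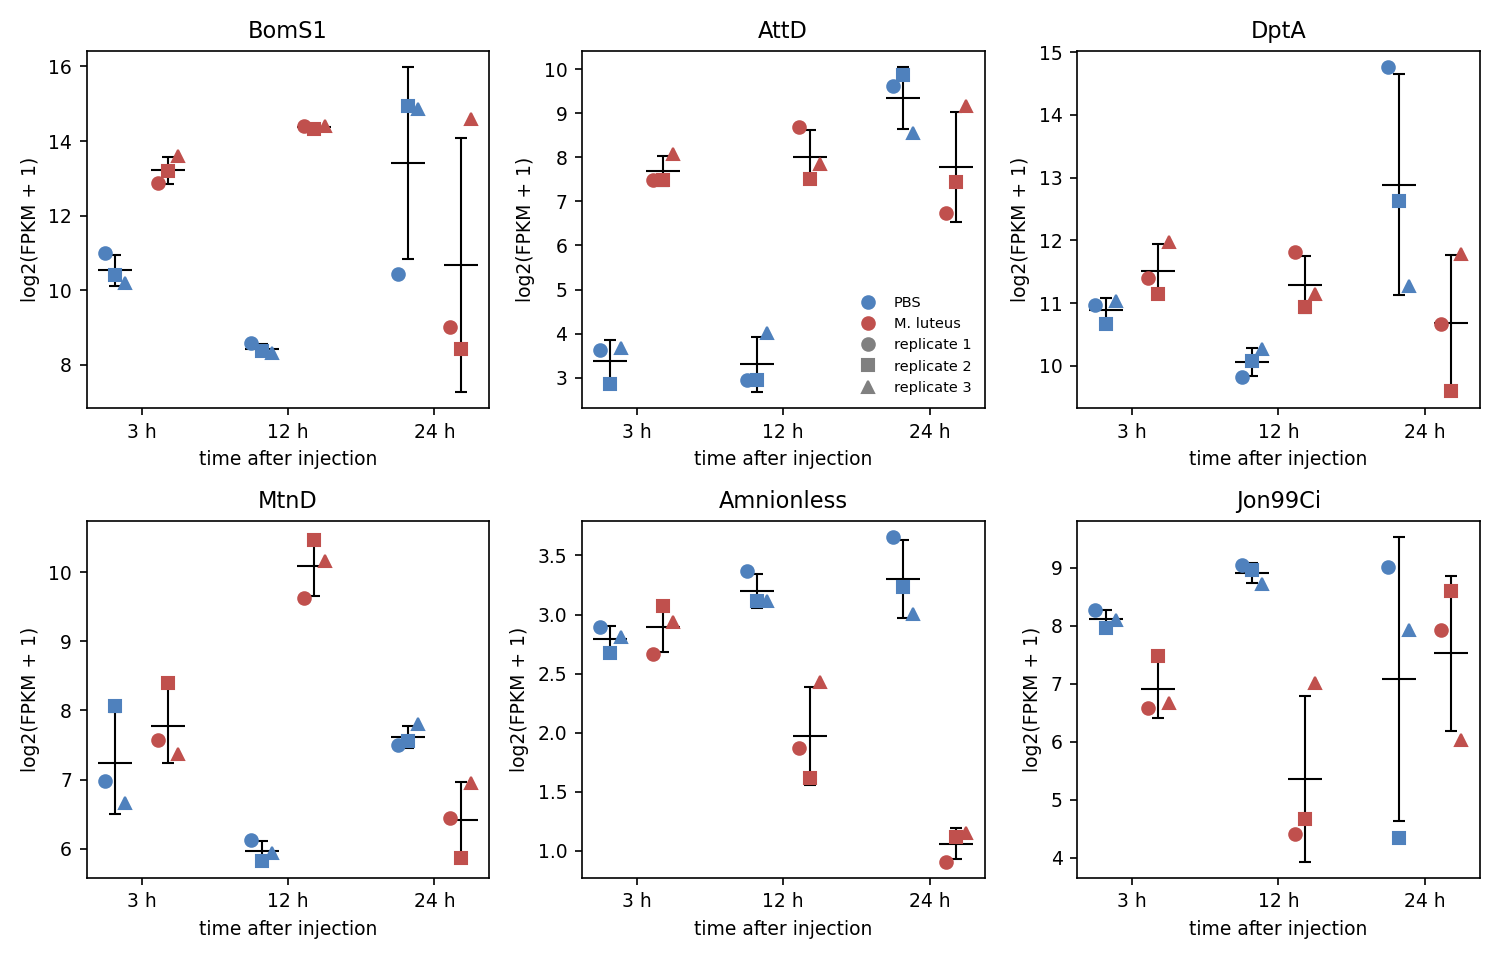
Log2(FPKM + 1) of BomS1, AttD, DptA, MtnD, Amnionless and Jon99Ci in each library, by time; colour gives the treatment, marker shape the replicate number, and lines and bars the mean and SD of 3 libraries. BomS1 averaged 21276 FPKM after M. luteus and 345 after PBS at 12 h, while at 24 h its libraries spread widely within both labels.

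The responses at 3 and 12 h overlapped. In all, 146 genes were higher at both times, against 17.3 for independent sets, 59 were lower at both, against 9.98, and 9 went opposite ways, against 29.3. Both contrasts use the same estimate of spread for a gene, which by itself can raise the number called at both, so independent sets are a low baseline. The 205 genes shared in direction were 514 without the 24 h libraries, 64, 94 and 123 without M. luteus 12 h replicates 1, 2 and 3, and 94, 87 and 85 without PBS 12 h replicates 1, 2 and 3. They were 68 without M. luteus 3 h replicate 3, 114 and 132 without PBS 3 h replicates 2 and 3, 310 without PBS 24 h replicate 1 and 319 without M. luteus 24 h replicate 3. Across the 12493 genes the log2 changes had a Pearson r of 0.44 and a Spearman rho of 0.20, computed over genes, which are not independent replicates. The change in response from 3 to 12 h was tested directly and passed for 76 genes, 23 higher and 53 lower at 12 h. The response of MtnD was higher at 12 h by 3.59 ± 0.50 (SE, adjusted p = 0.0091) and that of MtnA by 2.01 ± 0.29, and Nepl12, of the neprilysin family, by 1.65 ± 0.21. LysB differed by -2.69 ± 0.26 (adjusted p = 0.00056), having risen at 3 h and fallen at 12 h. LysC, assembled over the same span, differed the opposite way, so the division of reads between these similar genes leaves the LysB change uncertain. The cuticle protein genes Cpr92F and Acp65Aa differed by -3.31 and -2.88. Of 22 cuticle genes 3 were lower and none higher (10 and 1 when adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.86 with an estimated correlation). No flight muscle gene of 21 passed in limma (14 lower when adjusted over the list alone), with camera adjusted p = 7.2e-09 and adjusted p = 0.37 with an estimated correlation. No bomanin passed either, with a median difference of 2.07, whereas without the 24 h libraries 12 of 15 were higher. The 76 genes became 361 without the 24 h libraries, 10 without replicate 2 of either 12 h group, 20 without replicate 1 of M. luteus 12 h, and 19 and 20 without PBS 12 h replicates 1 and 3. They were 39 without PBS 3 h replicate 3, 20 without M. luteus 3 h replicate 3, 41 without PBS 24 h replicate 3 and 120 without M. luteus 24 h replicate 3. With the replicate number as a block, 26 genes passed, 9 higher and 17 lower.

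At 24 h, the libraries labelled M. luteus were lower than those labelled PBS in most of the genes that differed. Amnionless (FBgn0025686, chromosome 2L, 283385 to 291795) and Cubn, which encode the receptor pair for protein uptake in nephrocytes, were at 1.09 ± 0.19 against 9.03 ± 2.35 FPKM and at 0.95 ± 0.05 against 3.81 ± 0.87 (SD, n = 3 each). Their log2 changes were -2.24 ± 0.19 (SE, adjusted p = 0.00011) and -1.29 ± 0.16 (adjusted p = 0.0014), and Cubn2 changed by -1.32 ± 0.16. Amnionless was at 11.6, 8.43 and 7.04 FPKM in the libraries labelled PBS and at 0.88, 1.18 and 1.23 in those labelled M. luteus. At 12 h these 3 genes had also been lower after M. luteus, by log2 changes of -1.23 ± 0.19, -1.31 ± 0.16 and -1.28 ± 0.16 (adjusted p = 0.0033, 0.00064 and 0.00071). Their 12 h values, and Cubn and Cubn2 themselves, were chosen after the values were seen. Over all genes called at both 12 and 24 h, 67 went opposite ways, against 15.03 for independent sets, 40 were lower at both, against 16.9, and 1 was higher at both. With 3 h, 96 went opposite ways, against 15.7, 11 were lower at both, against 7.18, and 1 was higher at both. The spread shared by the contrasts makes these baselines low as well. Of 27 genes that were higher under the M. luteus label, 1 differed at least 2-fold, CG33664, at 9.94 ± 3.70 against 0.16 ± 0.17 FPKM.

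The bomanins at 24 h were split within both labels. BomS1 was at 1395, 31247 and 29851 FPKM in the libraries labelled PBS replicates 1, 2 and 3, and at 518, 344 and 24582 FPKM in those labelled M. luteus replicates 1, 2 and 3. Its difference was -2.74 ± 1.30 with an adjusted p of 0.273. The antimicrobial peptide list had means of 8.10, 7.72 and 6.98 on the log2 scale in the libraries labelled PBS and 6.07, 5.74 and 6.96 in those labelled M. luteus, so that M. luteus replicate 3 stood above replicates 1 and 2 here too, while PBS replicate 1 was the highest. The cecropin CecB changed by -2.87, PGRP-LB, an enzyme that degrades peptidoglycan, by -2.03, and Tsf1 by -1.51. CecB and PGRP-LB fell by more than the last gene named by the rule at 24 h (-1.93) but were not named. Each therefore either did not pass the threshold or overlapped between the labels. PGRP-SC2 was at 214 ± 124 against 930 ± 505 FPKM. Of 18 extracellular recognition proteins, proteases and serpins upstream of Toll, 8 fell (12 when adjusted over the list alone), of 11 peptidoglycan recognition proteins 6 (8 when adjusted over the list alone), of 19 antimicrobial loci 4 (13 when adjusted over the list alone) and of 10 iron and metal genes 5 (9 when adjusted over the list alone). None of these lists held a gene that rose. Their camera adjusted p-values were 3.5e-08, 1.2e-07, 2.2e-07 and 2.7e-07, and each had adjusted p = 0.22 with an estimated correlation. Of the 15 bomanin loci none passed in limma and 3 were lower when adjusted over the list alone, with camera adjusted p = 1.3e-05 and adjusted p = 0.42 with an estimated correlation.

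An index was set with the mean of PBS at 12 h as 0 and that of M. luteus at 12 h as 1, as a median over genes. The genes were those changed at least 2-fold and past the threshold at 12 h in the fit without the 24 h libraries. Over 218 such genes raised at 12 h, the libraries labelled PBS 24 h lay at 0.43, 1.12 and 0.98. Those labelled M. luteus 24 h lay at 0.05, -0.01 and 0.91. The M. luteus 3 h libraries lay at 0.79, 0.81 and 0.89 and the PBS 3 h libraries at 0.22, 0.19 and 0.18. Over 285 genes lowered at 12 h, the libraries labelled PBS 24 h lay at 0.22, 1.31 and 0.71 and those labelled M. luteus 24 h at 0.60, 0.35 and 1.02, against 0.64, 0.58 and 0.68 for M. luteus 3 h and 0.33, 0.21 and 0.25 for PBS 3 h. When the fit used only the 24 h libraries, limma called 0 genes, with 2183 of 11977 at an unadjusted p under 0.05. The count of 417 was 69 without M. luteus 24 h replicate 1, 110 without M. luteus 24 h replicate 2, and 134 and 225 without PBS 24 h replicates 2 and 3. It was 936 without M. luteus 24 h replicate 3, 709 without PBS 3 h replicate 3 and 190, 21 higher and 169 lower, after quantile normalization; after median-of-ratios rescaling 32 were higher and 247 lower.

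**Figure D4:**
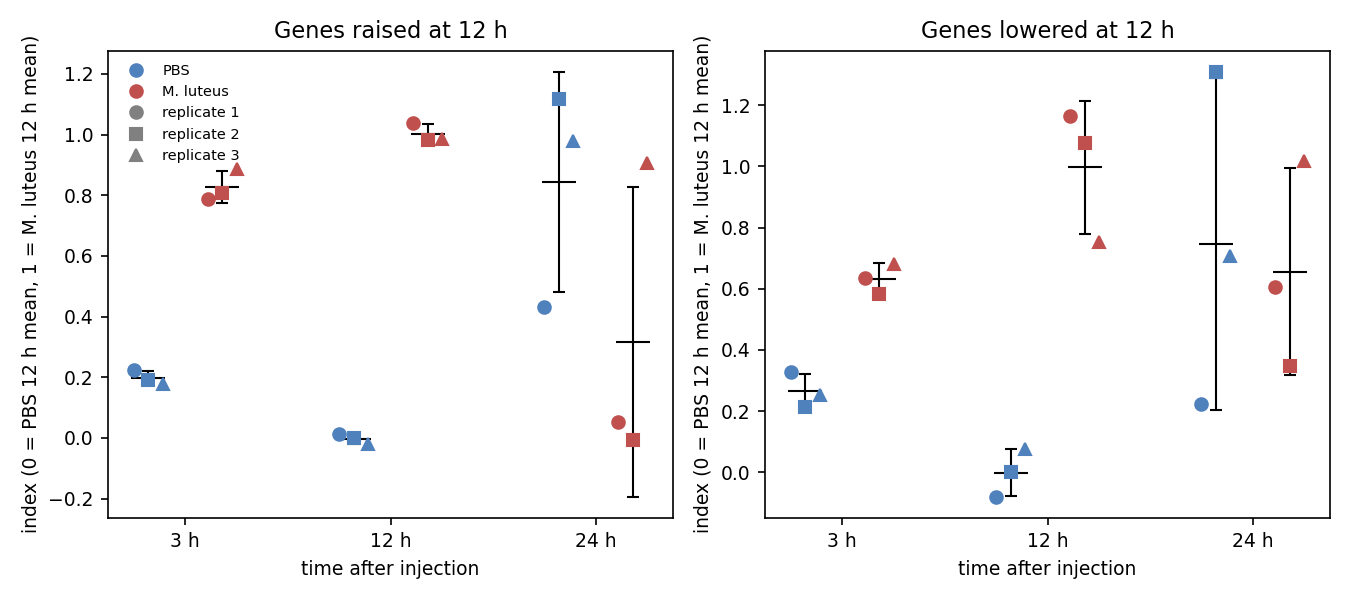
Position of each library on an index from the PBS 12 h mean (0) to the M. luteus 12 h mean (1), as a median over genes. The index covers 218 genes raised and 285 genes lowered at least 2-fold at 12 h in the fit without the 24 h libraries. Each point is a library. For the raised genes the libraries labelled PBS 24 h lie at 0.43, 1.12 and 0.98 and those labelled M. luteus 24 h at 0.05, -0.01 and 0.91, and for the lowered genes at 0.22, 1.31 and 0.71 and at 0.60, 0.35 and 1.02.

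Through these libraries, the response differed widely between 24 h and the earlier times. The difference between the 24 h and 3 h responses passed for 1050 genes, 145 higher and 905 lower, and that between 24 h and 12 h for 998, 243 higher and 755 lower. Of the former, 13.8% were higher, against 17.1% after median-of-ratios rescaling and 23.7% (214 higher and 690 lower) after quantile normalization. Of the latter, 24.3% were higher, against 34.1% and 37.8% after the same 2 scalings. BomT1 differed by -7.64 from its 3 h response and by -9.71 from its 12 h response. The first count was 687 without PBS 24 h replicate 2, 582 without M. luteus 3 h replicate 3, 641 and 625 without M. luteus 24 h replicates 1 and 2, and 495 fitted on those groups alone. The second was 1696 and 579 without PBS 24 h replicates 1 and 2, 529 without M. luteus 12 h replicate 1, 540, 531 and 1543 without M. luteus 24 h replicates 1, 2 and 3, 647 and 592 without PBS 12 h replicates 2 and 3, and 1512 without PBS 3 h replicate 3. Across genes, which are not independent replicates, the 24 h changes had a Pearson r of -0.32 with those at 3 h and -0.40 with those at 12 h.

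The mean of the infection effect over the 3 times, which includes the 24 h libraries as labelled, passed for 644 genes, 208 higher and 436 lower. In a fit without the 24 h libraries, the mean over 3 and 12 h passed for 1774, 903 higher and 871 lower. That fit changed the estimate of spread as well as the average. CG4716 was lower in all 3 M. luteus libraries than in the 3 PBS libraries at each time, with a mean effect of -1.13 ± 0.14 (SE, adjusted p = 0.00078). So were Adgf-D, an adenosine deaminase-related growth factor gene, at -0.91 ± 0.12, and Cyp304a1 at -0.75. Lim1, a homeobox transcription factor gene, was higher in the same sense, by 0.48 ± 0.06 (adjusted p = 0.00047). Of 11 hemocyte genes 6 fell and none rose (8 when adjusted over the list alone; camera adjusted p = 5.0e-06, and adjusted p = 0.34 with an estimated correlation). Of 42 P450 genes 9 fell and 1 rose (19 and 2 when adjusted over the list alone; camera adjusted p = 3.6e-06, and adjusted p = 0.40 with an estimated correlation). The secretion list had 6 higher of 22 and none lower (9 when adjusted over the list alone; camera adjusted p = 3.6e-06, and adjusted p = 0.40 with an estimated correlation). The mean count was 344 and 360 without M. luteus 12 h replicates 1 and 2, 356 without M. luteus 3 h replicate 3, and 422 and 974 without PBS 24 h replicates 1 and 2. It was 386, 411 and 413 without PBS 12 h replicates 1, 2 and 3.

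Within PBS, some clock genes differed between 3 and 12 h. In all comparisons within PBS, hour of day cannot be told from time after injection, and the series holds no uninjected group. The core clock gene timeless (tim, FBgn0014396, chromosome 2L, 3493976 to 3508119) was at 13.7 ± 1.01 FPKM in the 3 h libraries and 91.1 ± 2.81 in the 12 h libraries (SD, n = 3 each; log2 change 2.65 ± 0.10 SE, adjusted p = 6.7e-10). The clock genes vri and per rose by 1.76 ± 0.15 and 1.32 ± 0.14, and the clock output gene to by 1.20 ± 0.11. Of 12 circadian genes 4 rose and none fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.099 with an estimated correlation). Of 28 digestive proteases 3 rose and none fell (8 when adjusted over the list alone; camera adjusted p = 7.4e-06, and adjusted p = 0.68 with an estimated correlation), including Jon74E at 1.20. Mal-B1 changed by -2.88 ± 0.23, MtnE by -2.73 ± 0.48 and GstD2 by -1.77. In all 387 genes passed, 194 higher and 193 lower at 12 h (200 and 231 after median-of-ratios rescaling, 222 and 245 after quantile normalization), and 680 without the 24 h libraries. They were 106 without PBS 12 h replicate 2, 197 and 154 without PBS 12 h replicates 1 and 3, and 233 without PBS 3 h replicate 3.

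Between the libraries labelled PBS 24 h and those of PBS 3 h, 4784 genes differed, 2501 higher and 2283 lower at 24 h. The 24 h libraries of both labels stood apart, with 11853 to 11938 loci at 1 FPKM or more, against 11607 to 11846 at 3 and 12 h. A difference between libraries tied to 24 h therefore cannot be told from time. The balance turned with the scaling, to 2270 higher and 2501 lower after median-of-ratios rescaling and 2177 and 2485 after quantile normalization. The rises were led by AttD, at 5.96 ± 0.53 (SE, adjusted p = 8.1e-06), CG33462, at 5.59, and SPH93, at 5.47, in libraries where the infection index lay at 0.43, 1.12 and 0.98. Of 19 antimicrobial peptide loci 12 rose and none fell (16 when adjusted over the list alone; camera adjusted p = 4.8e-05, and adjusted p = 0.50 with an estimated correlation). Of 32 carbohydrate metabolism genes 20 fell and 1 rose (23 and 1 when adjusted over the list alone; camera adjusted p = 7.0e-06, and adjusted p = 0.50 with an estimated correlation). Flight muscle had 15 lower and 2 higher of 21, the same when adjusted over the list alone (camera adjusted p = 7.3e-05, and adjusted p = 0.50 with an estimated correlation). Of 27 testis genes 17 rose and none fell against the PBS 3 h group, which holds the library with female transcripts (19 when adjusted over the list alone; camera adjusted p = 7.0e-06, and adjusted p = 0.50 with an estimated correlation). The testis list averaged 5.94 on the log2 scale in that library, 6.21 and 6.31 in the other PBS 3 h libraries and 6.64 to 6.70 in those labelled PBS 24 h. The cuticle genes Cpr92F and Acp65Aa changed by -4.97 ± 0.42 and -4.13. Fitted on the PBS 3 h and 24 h libraries alone, 2205 genes passed. Between PBS 24 h and 12 h, 3729 genes differed, 1870 higher and 1859 lower (1724 and 1974 after median-of-ratios rescaling, 1577 and 2035 after quantile normalization), with IBIN, an infection-induced peptide gene, at 6.51 and Lsp2 at -3.39. Without PBS 12 h replicate 3 that count was 2393, and it was 2405 without PBS 24 h replicate 3.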

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

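The comparisons between times were planned, while every test of an explanation and every count of splits in this part was chosen after the result it measures had been seen.

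The response to M. luteus differed between 12 and 3 h for 76 genes, a difference tested directly. The response was higher at 12 h for MtnD (3.59), MtnA (2.01), the merged locus bgm/asRNA:CR44849 (1.92), CG4716 (1.75), lncRNA:CR44695 (1.69), Nepl12 (1.65), lncRNA:CR45323 (1.57), Nepl13 (1.33) and CG34043 (1.27), as log2 differences. Higher and lower refer here to the response with its sign, so a fall that shrank also counts as higher. CG4716 is such a case, with a log2 change of -2.24 at 3 h. LysC gave a fitted 9.40, which rests on groups listed at 0 and is no bound. LysB, assembled over the same span, went the opposite way, so the division of reads between them leaves both values uncertain. The response was lower at 12 h for lncRNA:CR45636 (-5.99, also resting on a group listed at 0), asRNA:CR11538 (-5.42), Cpr92F (-3.31), Acp65Aa (-2.88), CG14500 (-2.75), LysB (-2.69), Lcp1 (-2.01), CG1299 (-1.77), CG3819 (-1.77) and NimC2 (-1.62).

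Between 24 and 3 h, as labelled, 1050 genes differed in response. Higher at 24 h were Ser8 (4.07), PPO2 (3.64), phu (2.95), CG43055 (2.94), PPO1 (2.82), Lime (2.36), CG15358 (2.18), lncRNA:CR43417 (2.17), CG4950 (2.14) and CG42369 (2.14). Of these, PPO2, phu, CG43055, PPO1, Lime and CG42369 were among the named falls at 3 h, PPO2 by -2.67 and Lime by -2.16. Lower were CG42662 (-7.82), BomT1 (-7.64), CecB (-7.10), IBIN (-6.60), CG14499 (-6.54), AttD (-5.85), CecC (-5.74), CecA2 (-5.56), GNBP-like3 (-5.25) and CG6675 (-5.15).

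Between 24 and 12 h, as labelled, 998 genes differed in response. Higher at 24 h were Obp99b (7.85), asRNA:CR11538 (7.11), Lsp2 (5.55), Lsp1beta (5.54), CG18179 (4.88), CG6277 (4.41), Ser8 (4.31), Peritrophin-15a (4.10), CG8093 (3.94) and CG31091 (3.78). Of these, Obp99b, asRNA:CR11538, Lsp2, Lsp1beta, CG18179 and CG6277 were among the named falls at 12 h. Lower were CG4757 (-9.98), BomT1 (-9.71), SPH93 (-9.43), IBIN (-9.30), CG33462 (-9.10), BomS1 (-8.68), CG42662 (-8.62), GNBP-like3 (-8.37), BomS5 (-7.38) and Fst (-7.37).

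In the genes raised at 12 h, the libraries labelled PBS 24 h replicates 2 and 3 lay above those labelled M. luteus 24 h replicates 1 and 2 by a gap of 0.927 on the index, while over the genes lowered at 12 h the gap was 0.102 and M. luteus 24 h replicate 1 lay at 0.60, within the range of M. luteus at 3 h. Scaling between libraries was argued against for the raised genes, as their gap was 0.925 after median-of-ratios rescaling. The labelled split called 417 genes, and none of the 8 splits that are neither labelled nor exchanged called any in limma. This cannot decide on an exchange of these 4 libraries. The labelled split differs from the exchanged one only by trading PBS 24 h replicate 1 with M. luteus 24 h replicate 3. On the index of raised genes these lay at 0.43 and 0.91, closer together than any other pair across the exchanged split. Fitted on only the 24 h libraries, the labelled split called 0 genes in limma. PBS 24 h replicate 1 was itself the highest 24 h library in the antimicrobial peptide list. Of the genes called at both 12 and 24 h, 67 went opposite ways, against 15.03 for independent sets, 40 were lower at both, against 16.9, and 1 was higher at both. Independent sets are a low baseline here, since the contrasts share the spread of each gene. For the raised genes the exchange stays open, because the gap is the pattern itself and gives it no support of its own, and for the lowered genes the small gap leaves it open as well; the exchanged split called 968 genes, which points to a structure of the samples, and the biological state of the flies at 24 h, not tested, stays open too.

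PBS 3 h replicate 3 had the highest level of all 18 libraries in 21 of 21 loci of the female list. Female flies or their RNA in this sample are a candidate explanation that stays open, since this count restates the pattern and gives it no support of its own. Reads carried over from another library of the series were argued against, since the list averaged at most 0.65 in the other 17 libraries and 7.27 in this one. The labels name males in every group, so no biological explanation was tested.

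M. luteus 3 h replicate 2 had the lowest level of all 18 libraries in 18 of 18 loci of the eye list. Heads or eyes missing from the sample are a candidate explanation that stays open, since this count too restates the pattern. Scaling between libraries was argued against, since the median difference from the other M. luteus 3 h libraries was 0 over all genes tested and -4.85 over the eye list. The neuronal list lay at -1.14. No biological explanation was tested, since the labels give none.

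Splits of the libraries that ignore the labels were counted, the real one included. For the mean effect 1 of 100 splits gave as many genes (644, highest other 147), a share that argued against chance for that count. For the response between 12 and 3 h it was 1 of 100 (76, highest other 71). Between 24 and 3 h it was 2 of 100 (1050, highest other 1505) and between 24 and 12 h 1 of 100 (998, highest other 708). These splits also break the infection effect within each time. They therefore cannot decide whether the differences in response between times arose by chance. The larger 1505 points to a structure of the samples. For the comparisons of 2 groups, 10 splits are too few for a share under 0.05. Their real counts and highest others were 717 and 5 at 3 h, 986 and 1 at 12 h, and 417 and 968 at 24 h, where 2 splits gave as many. Within PBS they were 387 and 4 between 12 and 3 h, 4784 and 1 between 24 and 3 h, and 3729 and 0 between 24 and 12 h, with 2740, 5988 and 5200 genes at an unadjusted p under 0.05 in limma under the real split.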

How the results depend on the processing

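The settings here were planned, except leaving out the 24 h libraries, alone or with PBS 3 h replicate 3, which was chosen after seeing the data; all values are counts of genes past the threshold unless said otherwise. No named result reversed. For genes named because their groups did not overlap, this was fixed in advance when a library was left out or the pseudocount changed. For the 262 named gene results, 6664 values kept their call and direction, 972 kept the direction and lost the call, and 15 gained one. Pseudocounts, filters, rescaling and robust moderation left every count within 1.5 times its value, except 190 genes at 24 h after quantile normalization. Counts in order are infection at 3, 12 and 24 h, the mean effect, the response at 12 minus 3, 24 minus 3 and 24 minus 12 h, and PBS in the same 3 pairs. Array weights gave 2135, 2756, 3887, 2164, 1200, 3512, 3957, 1073, 7240 and 8016, and 749 genes shared by 3 and 12 h, but their fit did not converge and gave PBS 24 h replicate 3 a weight of 23.9. The added 2-fold minimum, which by construction can only remove genes, gave 178, 413, 91, 46, 44, 452, 522, 110, 570 and 517. With only the compared libraries, which are fewer, counts were 1976 at 12 h, 0 at 24 h, 361 for 12 minus 3 h, 495 for 24 minus 3 h, and 2205 for PBS 24 minus 3 h. At 24 h limma then had 2183 genes of 11977 at an unadjusted p under 0.05. Without the 24 h libraries the mean effect had 1774 genes, 12 minus 3 h had 361, PBS 12 minus 3 h had 680, and 514 were shared. Without these and PBS 3 h replicate 3, 12 h had 1932, the mean 1961, 12 minus 3 h 319, and 508 were shared. With the replicate number as a block, 12 minus 3 h had 26 genes; the same-number correlations after removing group means ran from -0.417 to 0.276, with 2 of 9 over 0.1, so the numbers gave no sign of pairing. With an estimated correlation camera called 0, 0 and 0 lists at 3, 12 and 24 h (8, 6 and 5 of 37 at an unadjusted p under 0.05), against 23, 22 and 18 with the preset one, and directional fry called 11 at 3 h. Without the 24 h libraries camera called 5 lists at 3 h and 5 at 12 h with an estimated correlation, of 25 and 25 with the preset one. Leaving out 1 library at a time gave 195 to 908 at 3 h, 220 to 1278 at 12 h, 69 to 936 at 24 h, 344 to 974 for the mean, 10 to 120, 582 to 1344 and 529 to 1696 for the responses between times, and 106 to 520, 3584 to 4853 and 2393 to 4485 within PBS. Shared genes ran from 64 to 319, against 205, and lists from 23 to 25, 19 to 25 and 18 to 23. Beyond the effects of construction named here the cause was not tested. Depth is unknown, so its part in the low-level genes cannot be given.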

Other observations

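The groups in this part come from lists that were planned, and the highest library at 24 h was picked after its values had been seen. Genes for opsonins and phagocytosis moved both ways at 12 h: of 12, 4 rose and 2 fell (4 and 4 when adjusted over the list alone), with a camera adjusted p of 0.661. The thioester protein genes Tep2 and Tep4 rose by 2.44 ± 0.32 and 1.75 ± 0.39 (SE, n = 3 each) and the secreted nimrods NimB1 and NimB2 by 2.16 ± 0.49 and 1.09 ± 0.24, while the membrane receptor gene NimC1 changed by -1.59 ± 0.30. Tep2 had already risen by 1.92 ± 0.32 at 3 h. Of 27 odorant-binding protein genes 4 fell and none rose at 12 h (5 when adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.28 with an estimated correlation), including Obp83cd at -1.73 ± 0.25.

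Some metabolic and stress genes changed as well. Tps1, which makes trehalose, the main blood sugar, was among the 5 carbohydrate genes that fell at 12 h, at -1.10 ± 0.29. Of 14 genes of amino acid and one-carbon metabolism 3 fell at 12 h and none rose (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.28 with an estimated correlation), among them the glutamine synthetase gene Gs2 at -0.62 ± 0.14. Thor, the inhibitor of cap-dependent translation known as 4E-BP, rose by 1.90 ± 0.39, and the stress gene Gadd45 rose at 3 and 12 h, by 1.60 ± 0.39 and 2.12 ± 0.39. At 3 h the heat shock gene Hsp67Bc rose by 1.22 ± 0.21 and Hsp83 changed by -0.52 ± 0.09. Of 15 genes of the small RNA machinery, which includes the makers of microRNAs, 1 rose at 3 h (also 1 when adjusted over the list alone), AGO2, the argonaute of RNA interference, by 0.53 ± 0.09 (adjusted p = 0.0030).

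In the 24 h libraries, PBS 24 h replicate 1 stood highest in DptA (27818 FPKM), edin (9864) and TotA (2869). Groups did not overlap in 22.5%, 35.9% and 25.6% of the genes tested at 3, 12 and 24 h, where chance gives 10% for a single gene with 3 against 3; genes move together, so these shares are no test.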
